A study of Homo sapiens with 6 samples.

How the data were processed

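Gene expression was measured in 6 samples of Hep3B, an established human liver cancer cell line, with Illumina bead arrays. Each array carries 47323 probes, short oligonucleotides on beads that bind labelled copies of a transcript. Per the labels' protocols, the cells were grown in medium with 10% serum, total RNA was extracted, and biotin-labelled RNA was hybridised. The samples were grouped by their titles into 3 groups of 2: vector control, wild-type SULF2 and SULF2 with the N491K change, called the mutant here. How the constructs were introduced is not given in the sources used here, nor is whether the 2 samples of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

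The authors deposited one table of probe intensities on a linear scale, not normalised, with a detection p-value for each probe and array. That detection p-value, deposited beside each intensity, says how the probe compares with the background probes of its array. The deposited series value table holds log2 values. They equal the log2 of the un-normalised intensities (largest absolute difference 5.0e-09), so these log2 values carry no normalisation between arrays. The scanner software and its settings are not given in the sources used here. No slide or scan date was used, because the files gave none, so an effect of slide or of cell lot cannot be separated from the groups. 

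The median intensity was 91.6 and 78.7 on the vector arrays, 84.3 and 78.0 on the wild-type arrays and 84.0 and 83.3 on the mutant arrays. Between 40.4% and 41.4% of the probes were detected (detection p-value under 0.05) on an array. The number of arrays, 2 per group, limits the precision of every value.

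Intensities were corrected for background with the normal-exponential model, using the detection p-values in place of control probes and an offset of 16, then quantile normalised between arrays and converted to log2 (the neqc function of limma 3.58.1 in R 4.3.3). Probes with a detection p-value under 0.05 on at least 2 of the 6 arrays were kept, in whichever group, which left 20935 probes. Where several kept probes named one gene, the probe with the highest mean over all 6 arrays stood for it. This gave 16213 genes. A probe was taken as not above background in a group when it was not detected on any array of that group. Its fold is then given as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own. Such a bound holds under this background correction only. The lowest detected signals lay between 5.09 and 5.13 on the log2 scale.

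In the platform's annotation 30113 probes had 1 gene symbol, 8 had several and 17202 were not listed. No gene was named from a probe with several. Symbols were updated through gene identifiers in a RefSeq gene table (assembly GRCh38.p14), and probes absent from the annotation kept the symbol given in the deposited file. Of the genes tested, 12022 had a current symbol and 4191 only the file's symbol, which can be old. No coordinates are printed, since the files name no genome build. 92 spike-in probes were left out of the tests.

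One linear model with the 3 groups was fitted to all 6 arrays with limma's lmFit and eBayes, so that the groups shared one estimate of the spread (3 residual and 6.44 prior degrees of freedom, prior SD 0.178 on the log2 scale). The 3 comparisons were wild type against vector, mutant against vector and mutant against wild type. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p of a single gene is from this two-sided limma test. 27 gene lists were fixed before the data were examined. Those with at least 5 tested genes (24 lists) were tested against the other genes with limma's camera, at its preset correlation between genes of 0.01, with adjustment over the lists of a comparison. The tests were repeated with the correlation estimated per list, with fry, which asks whether a list's genes move on balance one way, and with camera on ranks. With an estimated correlation camera also refers its statistic to the 3 residual degrees of freedom, far fewer than with the preset. Its p can therefore rise where the estimate is no higher than the preset.

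The genes named were chosen by a rule fixed before the data were examined. It takes SULF2 and SULF1, then for each comparison up to 12 called genes in each direction by fold whose arrays did not overlap between the groups. Where fewer were called in a direction, the genes next by unadjusted p, up to 5, are given as values that did not pass. For each list it takes up to 4 called members or, for a list called with no called member, 2 members with the smallest p. 3 uncharacterised loci were skipped by the rule. Genes named beyond it are said to be so, and 1 gene that the rule takes is not reported here.

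The fit was tested on simulated data with known changes planted in the mutant group, over the same 16213 genes. In mutant against vector, 58.2% of planted 2-fold changes and 95.5% of planted 3-fold changes were called, and 1.5% of planted 1.5-fold changes. In mutant against wild type the corresponding shares were 55.2%, 93.9% and 7.5%. Smaller changes than 2-fold were thus mostly out of reach of a single-gene test here. These shares hold for as many changes as were planted (67 at 1.5-fold, 67 at 2-fold and 66 at 3-fold). With fewer changed genes the adjusted threshold is stricter, so larger changes can be missed too. In wild type against vector, where none was planted, CKM at 2.82-fold did not pass (limma adjusted p = 0.0622). 

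Alternatives were tried for the background correction, the normalisation, the filter on dim probes, the probes of a gene, the moderation, the samples in the fit, the replicate number as a block, each array left out in turn, the threshold and the set test. No identical arrays were found: the correlation of log2 values between the 2 arrays of a group was 0.9927 in vector, 0.9901 in wild type and 0.9928 in the mutant. The wild-type arrays thus agreed less with each other than with some arrays of other groups, the first with the second mutant array (0.9915) and the second vector array (0.9912), and the second with the first vector array (0.9922). Both comparisons against vector share 2 arrays, so their correlation was set beside 100 simulations of unchanged groups.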

Results

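The series compared Hep3B liver cancer cells carrying a vector, wild-type SULF2 or the N491K mutant of SULF2. SULF2 is an extracellular enzyme that removes sulfate groups from heparan sulfate, the sugar chains that bind growth factors, chemokines and Wnt proteins at the cell surface. The study's title concerns SULF2 and the response of liver cancer to sorafenib, a kinase inhibitor. The labels name no drug treatment for these 6 arrays, so the comparisons ask how the SULF2 state relates to gene expression. 16213 genes were tested on 2 arrays per group.

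SULF2 transcript was the first check of the labels. Its probe ILMN_1686981 was not above background in vector cells (log2 level 4.38 ± 0.01, SD, n = 2). It was detected on every array of the other groups, at 7.53 ± 0.47 (SD, n = 2) with wild-type SULF2 and at 7.20 ± 0.03 (SD, n = 2) with the mutant. SULF2 was thus at least 5.41-fold higher in wild-type cells (limma adjusted p = 0.00115) and at least 4.31-fold higher in mutant cells (adjusted p = 0.00104) than in vector cells. Mutant and wild-type cells did not differ past the threshold (log2 change -0.33 ± 0.21, SE, adjusted p = 0.767). The other SULF2 probes were not detected on any array, and no probe reads the N491K change itself. SULF1, the related sulfatase, was detected on no vector array and on 1 of the 2 arrays of each SULF2 group, so no fold is given. It was not called against vector in wild-type or mutant cells (limma adjusted p = 0.987 and 0.778), nor between them (0.915).

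Wild-type SULF2 against vector asked what the enzyme's expression alone goes with. SULF2 itself was the 1 gene called, with 1086 genes at an unadjusted p under 0.05 where chance would give 811. The count was 23 without background correction or with an offset of 50, 25 with trend and robust moderation and 34 on the deposited values, which are not normalised between arrays. Next by p on the higher side, and not past the threshold, were CKM (muscle creatine kinase, log2 change 1.49 ± 0.17, SE), HAMP (the iron hormone hepcidin, 1.20 ± 0.16), EDN1 (endothelin, 1.09 ± 0.17), NPPB (a natriuretic peptide detected on 1 of the 2 vector arrays, too near background for a size) and KRT19 (a keratin of bile duct cells, 0.87 ± 0.15). On the lower side they were LCN2 (lipocalin, a secreted iron-siderophore binder, -1.24 ± 0.16), MEP1A (a meprin protease, -1.03 ± 0.16), AGR2 (an endoplasmic reticulum protein, -0.99 ± 0.17, and -0.63 on the mean of its kept probes), GPAM (a glycerolipid synthesis enzyme, -0.96 ± 0.16) and RENBP (renin-binding protein, not above background with wild-type SULF2 and at least 1.74-fold lower). The smallest limma adjusted p among these 10 was 0.0622, for CKM. CKM, HAMP, EDN1, KRT19, LCN2, MEP1A and AGR2 passed in each of the first 3 of those settings.

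Small shifts of whole gene groups passed camera's test in wild-type cells. The NF-kB inflammatory genes were lower as a group, 17 of the 20 tested members lying below 0 with a median log2 change of -0.139 (adjusted p = 0.00732, and 0.473 with an estimated correlation). None was called over all genes, and 2, LCN2 and ICAM1 (a leukocyte adhesion molecule, -0.83 ± 0.18, SE), were lower when adjusted over the list alone. The ATF4/CHOP stress response was higher as a group, with 19 of 27 members above 0 (median 0.122, adjusted p = 0.015, and 0.473 with an estimated correlation). Its members with the smallest p were NUPR1 (a stress-induced chromatin protein, 0.69 ± 0.15, SE) and PHGDH (serine synthesis, 0.61 ± 0.16), which passed when adjusted over the list alone. Cholesterol and lipid synthesis was lower, with 22 of 28 members below 0 (median -0.123, adjusted p = 0.015, and 0.789 with an estimated correlation). ELOVL6, a fatty acid elongase, stood at -0.61 ± 0.17 and FADS1, a desaturase, at -0.40 ± 0.16 (SE). In mutant cells against the same vector arrays, ATF4/CHOP (median 0.141) and cholesterol and lipid synthesis (-0.156) shifted similarly. Neither passed there (camera adjusted p = 0.138 for each) or between mutant and wild type (medians 0.036 and 0.009).

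Heparan sulfate synthesis and sulfation, the pathway that makes SULF2's substrate, was also lower in wild-type cells, with 18 of 22 members below 0 (median -0.12, adjusted p = 0.0446, and 0.473 with an estimated correlation). HS3ST3A1, a heparan sulfate sulfotransferase, stood at -0.98 ± 0.17 (SE), the 1 member that passed when adjusted over the list alone, and EXTL3, a chain-starting glycosyltransferase, at -0.35 ± 0.15. The shift was similar in mutant cells against the same vector arrays, with 15 of 22 members below 0 (median -0.105), but did not pass (camera adjusted p = 0.116). HS3ST3A1 passed over the list alone there too. Between mutant and wild type the list did not pass (median -0.046, camera adjusted p = 0.967). Another 4 lists passed narrowly in wild type against vector, each at an adjusted p of 0.04997, and with an estimated correlation at 0.473 for FGF/ERK output, 0.789 for receptor tyrosine kinases and ribosomal proteins and 0.816 for ER chaperones. FGF/ERK output genes had 15 of 21 members below 0 (DUSP5, an ERK phosphatase, -0.81 ± 0.16; HBEGF, an EGF receptor ligand, -0.47 ± 0.16). ER chaperones had 16 of 21 below 0 (PDIA4 -0.40 ± 0.16; MANF -0.31 ± 0.16; with an array left out between -0.54 and -0.26 and between -0.43 and -0.2). Receptor tyrosine kinases and ligands had 16 of 21 below 0 (HBEGF, and PDGFA, detected on 1 of the 2 wild-type arrays and too near background for a size), and ribosomal proteins had 56 of 75 above 0 (RPL14 0.41 ± 0.17; RPS26 0.30 ± 0.16). None of these 8 calls held with an estimated correlation, a setting that also uses fewer degrees of freedom. The estimates were 0.047 for ribosomal proteins, 0.084 for receptor tyrosine kinases, 0.15 for cholesterol and lipid synthesis and 0.179 for ER chaperones. They were below the preset 0.01 for NF-kB (-0.028), ATF4/CHOP (-0.031), FGF/ERK output (-0.013) and heparan sulfate synthesis (0). For those lists correlation between genes thus does not account for the higher p. The wild-type arrays correlated less with each other (0.9901) than the second of them did with the first vector array (0.9922). Without the second vector array 0 lists were called in this comparison, without the first wild-type array 1 (NF-kB), without the first vector array 7, and without either mutant array, which enters through the shared spread, 3.

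The mutant against vector comparison asked what changed with mutant SULF2. 31 genes were called, 27 lower and 4 higher, and in each both mutant arrays lay beyond both vector arrays. LCN2 fell 13.1-fold, from a log2 level of 12.37 ± 0.17 to 8.67 ± 0.06 (SD, n = 2; limma adjusted p = 1.88e-05). MMP7, the protease matrilysin, fell at least 7.99-fold, from 8.11 ± 0.15 to below background on both mutant arrays (limma adjusted p = 3.33e-05). The chemokine genes CXCL6, a neutrophil attractant, and CXCL10, an interferon-induced T cell attractant, fell 3.61-fold and 3-fold (limma adjusted p = 0.0146 and 0.0172). 

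The other lower genes named by the rule were PTPN20 (a tyrosine phosphatase, at least 2.83-fold), SERPINA3 (the acute-phase protein antichymotrypsin, 2.68-fold), PLAU (urokinase, 2.66-fold), SPINK1 (a secreted trypsin inhibitor detected on 1 of the 2 mutant arrays, too near background for a fold), MIR3142HG (a microRNA host gene, 2.62-fold), AZGP1 (a secreted zinc-binding glycoprotein, 2.55-fold), LTB (lymphotoxin beta, 2.52-fold) and FZD9 (a Wnt receptor, 2.51-fold). Besides SULF2, the genes that rose were CYP24A1, the enzyme that inactivates vitamin D (2.48-fold, limma adjusted p = 0.0259), S100P, a calcium-binding protein (2.24-fold, adjusted p = 0.0226), and an uncharacterised locus, LOC643824, outside the naming rule (at least 2.05-fold, adjusted p = 0.0146). Next by p, not past the threshold, were EDN1 (log2 change 1.09 ± 0.17, SE), HAMP (0.95 ± 0.16), CKM (0.94 ± 0.17), KRT19 (0.88 ± 0.15) and SCNN1A (a sodium channel subunit, 0.85 ± 0.15). 8 of the called genes had several kept probes, and all probes of each gave the same sign. A second probe of KLHL28, a called gene outside the rule, stood at -0.12 (unadjusted p = 0.546).

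**Figure D1:**
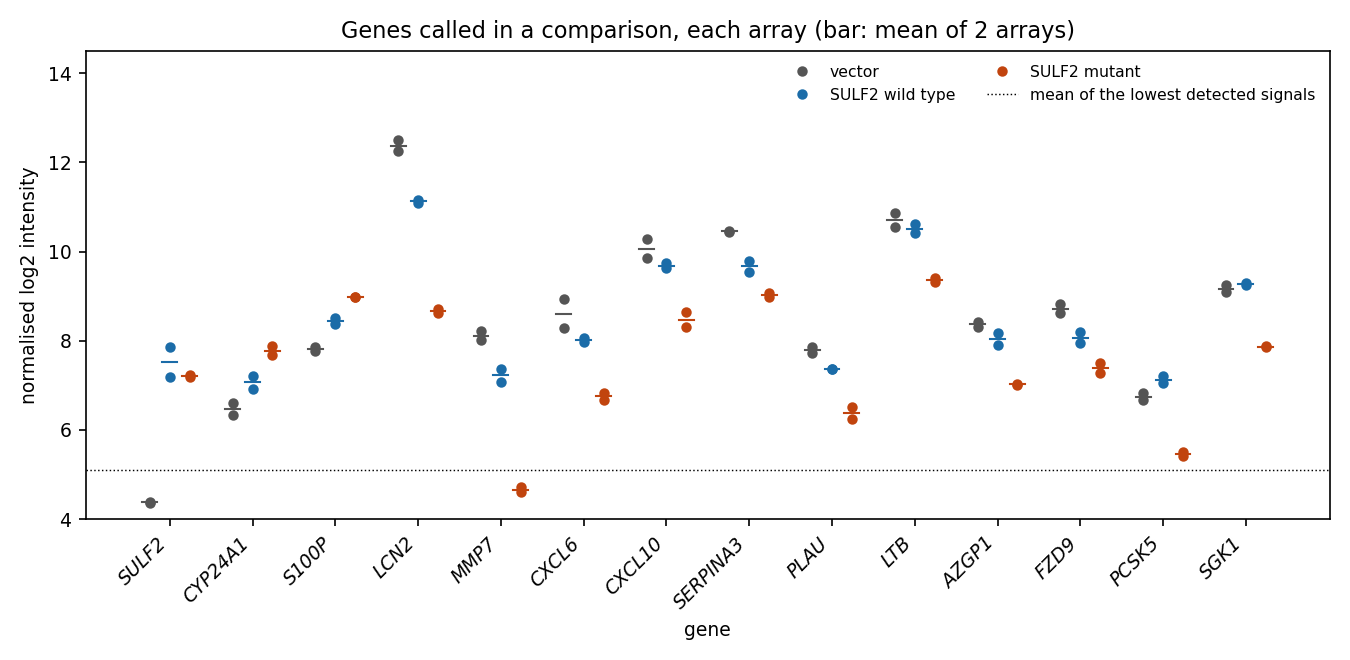
Normalised log2 intensity (vertical axis) of 14 genes called in a comparison, with 1 point per array, a bar at the mean of the 2 arrays of a group, and the dotted line at the mean of the lowest detected signals. LCN2 stands at 12.25 and 12.49 on the vector arrays, 11.10 and 11.16 on the wild-type arrays and 8.71 and 8.62 on the mutant arrays, while SGK1 stands at 9.25 and 9.09, 9.25 and 9.29, and 7.86 and 7.88.

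The NF-kB inflammatory genes were lower together in mutant cells. All 20 tested members lay at or below 0, with a median log2 change of -0.497 (camera adjusted p = 6.3e-14, and 0.0784 with an estimated correlation). LCN2, CXCL6 and LTB were called over all genes, and 10 members, all lower, were called when adjusted over the list alone. Among those 10, and named, like the next pair, outside the rule after their values were seen, were ICAM1 (-1.10 ± 0.18, SE), CXCL2 (a neutrophil chemokine, -0.99 ± 0.16), TNFAIP3 (an inhibitor of NF-kB signalling, -0.73 ± 0.17) and SOD2 (the mitochondrial superoxide dismutase, -0.57 ± 0.15). CXCL8 (0.00 ± 0.17) and the NF-kB subunit gene NFKB2 (-0.04 ± 0.16) were close to 0 and did not pass. 

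**Figure D2:**
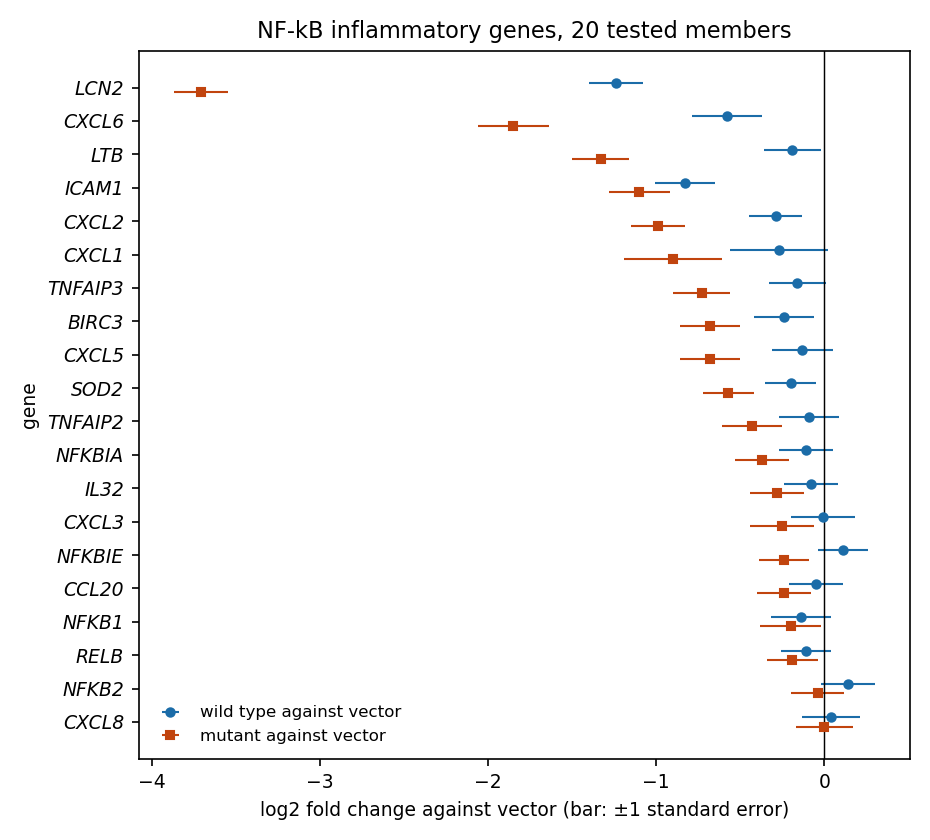
Log2 fold change against vector (horizontal axis, bars ±1 SE) of the 20 tested NF-kB inflammatory genes, in wild-type cells (circles) and mutant cells (squares), ordered by the change in mutant cells. LCN2 stands at -3.71 in the mutant and -1.24 in wild type, CXCL6 at -1.85 and -0.58, and LTB at -1.33 and -0.19.

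Interferon response genes were lower as a group in mutant cells, with 15 of 21 members below 0 (median -0.199, camera adjusted p = 0.018, and 0.57 with an estimated correlation). CXCL10 was the 1 called member, and without it, a choice made after seeing the data, the adjusted p was 0.109, within a range of 0.00712 to 0.57 over all alternatives. ER chaperones were lower, with 17 of 21 members below 0 (median -0.193, adjusted p = 0.0127, and 0.57 with an estimated correlation), and none was called; PDIA4 stood at -0.43 ± 0.16 and MANF at -0.39 ± 0.16 (SE). Ribosomal proteins were higher, with 59 of 75 members above 0 (median 0.095, adjusted p = 0.00817, and 0.57 with an estimated correlation; RPS7 0.60 ± 0.22). Cell cycle and mitosis genes were higher, with 34 of 42 members above 0 (median 0.144, adjusted p = 0.0112, and 0.57 with an estimated correlation; CCNA2, a cyclin, 0.35 ± 0.15, CENPA, a centromere histone, 0.39 ± 0.19, between 0.23 and 0.55 with an array left out). No member of these last 3 lists was called, whether over all genes or adjusted over the list alone. Each of these 4 calls was also lost without the second vector array (adjusted p 0.103 to 0.151) and without the first mutant array (0.0678 to 0.151).

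The count of 31 genes depended on single arrays and on the processing. It was 3 (LCN2, MMP7 and SULF2) without the second vector array or without the first mutant array, 4 without the first vector array, and 6 without the second mutant array. It was 3 without a filter on dim probes or with the replicate number as a block, 163 with a stricter filter, 316 without background correction, 309 with an offset of 50, 317 on the deposited values and 359 with a spread that follows the expression level (eBayes with trend and robust).

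Mutant against wild type compared cells in which SULF2 transcript did not differ past the threshold. 5 genes were called, and all 5 were also called, in the same direction, against vector. MMP7 fell at least 4.32-fold (limma adjusted p = 0.000511) and LCN2 5.51-fold (adjusted p = 0.000511). PCSK5, a proprotein convertase, fell 3.16-fold (adjusted p = 0.00805) and SGK1, a serum- and glucocorticoid-regulated kinase, 2.64-fold (adjusted p = 0.0195). The other kept probes of SGK1 stood at a log2 change of -0.93, against -1.40 for the probe shown. Without background correction the log2 changes were smaller, at -0.95 for PCSK5 (-1.66 in the main fit) and -1.44 for MMP7 (-2.56). LOC643824, outside the naming rule, rose at least 2.01-fold (adjusted p = 0.0231). 

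Next by p on the lower side, and not past the threshold, were ALDH8A1 (an aldehyde dehydrogenase, -1.19 ± 0.15, SE, limma adjusted p = 0.0522), IFNLR1 (an interferon lambda receptor chain, -1.17 ± 0.17, and -0.63 on the mean of its kept probes), LTB (-1.14 ± 0.17), LITAF (a lysosomal membrane protein, -1.04 ± 0.15) and GBP2 (an interferon-induced GTPase, -1.03 ± 0.16). On the higher side they were ASAP3 (1.11 ± 0.20), MPP2, RSF1 (a chromatin remodelling factor), GPAM (0.85 ± 0.16) and SCNN1A (0.80 ± 0.15). MPP2 and RSF1 were each detected on 1 of the 2 wild-type arrays, too near background for a size.

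The NF-kB inflammatory genes were lower as a group in mutant than in wild-type cells, with all 20 members below 0 and a median of -0.343 (camera adjusted p = 1.67e-11, and 0.104 with an estimated correlation). LCN2 was called over all genes, and 6 members, all lower, when adjusted over the list alone: LCN2, LTB and, outside the rule, CXCL6 (-1.27 ± 0.21, SE), CXCL2 (-0.70 ± 0.16), CXCL5 (-0.54 ± 0.18) and TNFAIP3 (-0.57 ± 0.17). Interferon response genes were lower, with 17 of 21 members below 0 (median -0.162, adjusted p = 0.00875, and 0.319 with an estimated correlation; CXCL10 -1.21 ± 0.19, XAF1 -0.68 ± 0.19). Without CXCL10 their adjusted p was 0.0598, within a range of 0.00215 to 0.319 over all alternatives. Replication-dependent histone genes were lower, with 8 of 9 members below 0 (median -0.243, adjusted p = 0.00847, and 0.624 with an estimated correlation; H2AC20 -0.51 ± 0.22, between -0.79 and -0.23 with an array left out, and H2AC6, detected on 1 of the 2 mutant arrays and too near background for a size). Against vector the histone list passed in neither wild-type nor mutant cells (medians 0.16 and -0.099, camera adjusted p = 0.0559 and 0.393). FGF/ERK output genes were lower in wild type against vector (median -0.077) and not called in mutant against vector (median 0.046, camera adjusted p = 0.589). In mutant against wild type they were higher, with 15 of 21 members above 0 (median 0.151, adjusted p = 0.00847, and 0.319 with an estimated correlation). DUSP5 stood at 0.68 ± 0.16 and ETV4, an ERK-responsive transcription factor, at 0.40 ± 0.15 (SE). These 3 calls were also lost without the first wild-type array (0.0707 to 0.183) and without the first mutant array (0.0608 to 0.0956).

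The count of 5 genes was 2 without the second wild-type array or the first mutant array, 3 without any other single array, 12 on the deposited values, 13 with a stricter filter, 49 without background correction or with an offset of 50, and 91 with trend and robust moderation. MMP7 and LCN2 passed with each array left out, PCSK5 lost the call without any one wild-type or mutant array (adjusted p 0.0623 to 0.163), and SGK1 lost it without any one of the 6 arrays (0.0715 to 0.237).

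Other lists that bear on liver cell identity and on the study's theme did not pass in any comparison. Hepatocyte secreted proteins and metabolism had median log2 changes of 0.013, 0.074 and 0.06 in wild type against vector, mutant against vector and mutant against wild type. Drug and xenobiotic handling stood at -0.054, -0.025 and 0.049, apoptosis regulators at 0.021, -0.03 and -0.06, and Wnt/beta-catenin targets at -0.013, 0.063 and 0.004. Fibroblast and stellate cell markers and blood and endothelial markers each had 4 tested genes, too few for the set test, and none of these was called.

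Across genes, which are not independent replicates, the changes of wild type and of mutant against vector had a Pearson r of 0.553. Both use the same vector arrays, and simulated groups without any effect gave 0.482 to 0.514. Part of the excess of r may come from the shared controls. With a separate vector array for each comparison, a choice made after seeing the data, r was 0.179 and 0.181. The covariance, to which shared controls add the same amount with or without effects, was 0.0345 against a simulated median of 0.0228 (0.0216 to 0.0239), a difference of 0.0117, and 0.0147 and 0.0149 with the separate arrays.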

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

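Counts of called genes moved strongly with the processing, and direction mostly did not. In the order wild type against vector, mutant against vector and mutant against wild type, the counts were 1, 31 and 5 as reported. They were 23, 316 and 49 without background correction, 23, 309 and 49 with the normal-exponential correction at an offset of 50, and 25, 359 and 91 with trend and robust moderation. All 31 and all 5 genes were among the calls of each of these 3 settings. On the deposited log2 values, not normalised between arrays, the counts were 34, 317 and 12, of which 30, 311 and 10 were lower. There the median of all genes lay at -0.181, -0.105 and 0.066, so those splits hold a shift of the whole array. Probes detected on all 6 arrays at the stricter threshold gave 2, 163 and 13, a filter that removes SULF2 itself. Without a filter, 33661 genes were tested and mutant against vector fell to 3 genes. An adjusted p under 0.01 left 3 genes in mutant against vector and 3 in mutant against wild type. Only the 2 groups compared gave 3 in mutant against wild type. The cause of the moves was not tested beyond what these constructions show (fewer samples, more genes, a compressed background).

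Replicate numbers did not pair the samples: replicate differences correlated at -0.18 between vector and wild type, 0.12 between vector and mutant and -0.04 between wild type and mutant. With the number as a replicate block, mutant against vector gave 3 genes, mutant against wild type 3, and the wild-type lists 3. For vector and wild type alone the block gave 10 genes, and crossed numbers, an alternative chosen after seeing the data, gave 4.

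Leaving out each array in turn, where the lone array of a group is assumed to vary like the others, gave 1 to 2, 3 to 21 and 2 to 3 genes. In mutant against vector the count was 4 without the first vector array, 3 without the second, 21 without either wild-type array, 3 without the first mutant array and 6 without the second. In mutant against wild type it was 3 without either vector array, the first wild-type array or the second mutant array, and 2 without the second wild-type array or the first mutant array. Of the named genes called in mutant against vector, LCN2, MMP7 and SULF2 passed with each array left out, and the other called ones kept their direction but lost the call without the second vector array and without the first mutant array. Of 69 log2 changes of named genes (SULF1 and SULF2 left out), 0 to 2 moved by over 1.5 times with an array left out, 23 did, all to smaller changes, without background correction and 23 with the offset of 50, and 37 on the deposited values; none of them turned in direction. SULF2 was not above background in vector cells, so its changes against vector have no reliable size. Between mutant and wild type its log2 change ranged from -0.66 to 0, the value 0 arising without the first wild-type array. SULF1 turned to -0.07 in wild type against vector on the deposited values, to -0.01 without the first vector array and to -0.23 without the second wild-type array, and to -0.13 in mutant against wild type without the first wild-type array; with an array left out it ranged from -0.23 to 0.31 and from -0.13 to 0.41. It was near background and was called under none of the alternatives.

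Called lists numbered 8, 5 and 4 as reported. With estimated correlations they numbered 0, 0 and 0, and with fry 2, 2 and 2. The mutant lists against vector numbered 8 without background correction, 8 with the offset of 50 and 8 with the stricter filter, and the wild-type lists 3 with only the 2 groups compared. Leaving out an array gave 0 to 8, 1 to 6 and 1 to 5 lists. In both mutant comparisons the NF-kB list passed in 19 of 20 alternatives, the exception being the estimated correlation; without LCN2 (chosen, like the runs without CXCL10, after seeing the data) its adjusted p was 2.49e-11 and 4.41e-09. In wild type against vector it was 0.0314 without LCN2 and 0.0506 without the second vector array, within 2.67e-07 to 0.473 over all alternatives. The other 4 lists of mutant against vector were lost without the second vector array and without the first mutant array. The other 3 lists of mutant against wild type were lost without the first wild-type array and without the first mutant array. The correlation of the 2 effects against vector was 0.592 without background correction, 0.591 with the offset of 50, 0.588 with median scaling, 0.639 on the deposited values, 0.53 without a filter and 0.596 with the stricter filter, and 0.399 to 0.66 with an array left out. With a separate vector array for each comparison, an alternative chosen after seeing the data, it was 0.179 and 0.181. Slide as a block was not run, because the files gave no slide, and set tests under trend and robust moderation were not run. Signal over background limits the genes near the floor, SULF1 among them, whose changes have no reliable size.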

Other observations

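Several single members of other lists passed when adjusted over their list alone, though not over all genes, and those below were chosen after their values were seen. TGFBR3, a heparan sulfate-bearing TGF-beta co-receptor, was lower in both SULF2 groups against vector, at log2 changes of -0.89 ± 0.19 in wild type and -0.85 ± 0.19 (SE, n = 2) in the mutant. The heat shock protein gene CRYAB was higher in both, at 1.04 ± 0.20 and 0.78 ± 0.20, and so was KRT19. In the mutant against vector, KRT18 stood at 0.50 ± 0.15 and the tight junction gene TJP3 at -0.99 ± 0.16, so epithelial genes did not move one way. IGFBP3, a carrier of insulin-like growth factors, stood at -1.08 ± 0.20, the fibrinogen chain gene FGB at 0.84 ± 0.16, and the detoxification genes CYP1A1 and GSTA4 at 0.70 ± 0.16 and 0.67 ± 0.16.

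The called genes differed in where wild-type cells stood, seen after their values were known. LCN2, MMP7 and SERPINA3 stood between vector and mutant on the wild-type arrays, whereas SGK1, LITAF and GBP2 stood near vector, at changes of 0.10 ± 0.15, 0.07 ± 0.15 and -0.06 ± 0.16 (SE) in wild type against vector. HAS3, a hyaluronan synthase outside the naming rule, and AGR2 stood near the mutant, with log2 levels on the wild-type arrays of 5.39 and 5.61 and of 8.82 and 8.98. HAS3 lay at 5.31 and 5.38 on the mutant arrays, near the lowest detected signals, so its closeness may only reflect that floor. No test compared these classes.

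Of the tests below, the comparison with genes of like level, the chromosome draw for the lower genes alone, the last simulation and the test with the vector arrays taken in turn were chosen after earlier results were seen. More genes fell than rose in mutant against vector, 27 against 4. The first vector array was the brightest of the 6, which could leave a residue of scaling. The bound set beforehand, that the falls keep at least 0.75 of their size under every scaling and background alternative, was missed, with a lowest ratio of 0.738 without background correction, a setting that shrinks the SD of all changes to 0.723 of its size. On un-normalised values, though, tested genes of like level changed by a median of -0.118 and the 27 genes by -1.133. A shift this small in genes of like level argues against brightness as the whole size of the falls. The smallest excess of any of the 27 over its neighbours in level was -0.544, against a median SD of 0.193. That excess decides nothing, because the 27 were picked as lower on these arrays and called genes were left out of the neighbours. The split of 27 against 4 was not itself tested against brightness. A copy number difference at one chromosome as the whole cause is argued against too, since the fullest chromosome held 5 of the 26 placed called genes of both directions (SULF2 left out) and a share of 0.268 of 10000 random draws held as many on one, and for the lower genes alone it held 5 of the 24 placed and the share was 0.201. No biological explanation was tested, and other differences between cell lots, which the labels do not describe, stay open.

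A difference between cell lots could also shift a run of neighbouring genes. The largest median shift over 51 neighbouring tested genes was 0.153 in mutant against vector and -0.145 in wild type against vector, on the log2 scale. Shuffled gene orders gave a shift as large in a share of 0.385 and 0.105 of 1000 runs. The values argue against a copy number change of that length with a larger effect than these shifts, and changes over shorter runs stay open.

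The 27 genes that fell in the mutant were also lower in wild type against vector, 23 of them below 0, with a mean log2 change of -0.521 against -1.51 in the mutant. Both comparisons subtract the same 2 vector arrays, which may account for it. The simulation set beforehand, of unchanged groups, picked as many genes by the lowest simulated mutant change, not matched in size of fall. It gave -0.634 to -0.365, which includes the observed value. Its ratio of the mean wild-type change to the mean mutant change was 0.372 to 0.623, and the observed ratio of 0.346 lies below that. That simulation picks genes that differ by noise alone, so a further one planted changes in a simulated mutant (80 runs, median 23.5 called lower genes, 8 to 49). The planted changes were 0.85 of those observed, for genes at an unadjusted p under 0.05. It gave -0.241 to 0.00425, which leaves the observed value outside. It cannot decide, because the observed changes already hold noise of the vector arrays, planted here as true change. A version tried between the 2 simulations was void, because it fixed the genes and so centred on 0. The simulations disagree, so the vector arrays were taken in turn. The 27 lower genes with the smallest p against one vector array had a mean change in wild type against the other vector array of -0.486 (picked with the second) and -0.473 (picked with the first), where 10000 random lists of like level gave -0.09 to 0.107 and -0.086 to 0.118. 24 and 19 of the picked genes were among the 27 called. This argues against noise of single vector arrays as the whole cause, while a difference common to both vector arrays, such as of cell lot, stays open.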
